A study of Mus musculus with 4 samples.

How the data were processed

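Gene expression was measured by RNA sequencing in 4 libraries of mouse bone marrow-derived macrophages on the C57BL/6 background. Marrow cells had been differentiated with M-CSF, the macrophage growth factor, at 20 ng/mL for 7 days. They were then stimulated with interleukin 4 (IL-4) at 20 ng/mL for 24 h. There were 2 libraries from floxed control mice (Eif2ak3 fl/fl, here wild type) and 2 from mice that also carry LysMcre (here knockout). Total RNA was depleted of ribosomal RNA and made into stranded, randomly primed libraries for a HiSeq instrument. Unstimulated macrophages, which the study's design text also mentions, are not analysed here.

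The deposited values are FPKM, fragments scaled to the length of the feature and to the mapped fragments of the library, computed by the authors and given to 2 decimals, with 1 table per library. The authors' processing notes name HISAT, StringTie, Bowtie2, RSEM and the mm10 genome, without versions or the role of each tool. The annotation is not given, nor is whether reads were counted by strand. The smallest value listed is 0.01 FPKM, and a feature missing from a library was taken as 0. The tables hold no counts, so the depth of each library is unknown and no counting interval can be given; precision was judged from the spread between libraries.

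Features carried either an Entrez gene number or a locus identifier of the authors' own. Of 15114 Entrez-numbered genes listed in any library, 15094 matched a symbol in the RefSeq table for GRCm38.p6 and 20 did not. The other 76534 features could not be paired with a gene and did not enter the main comparison. They were used only in summaries of the libraries, in a fit on all listed features and where unnamed features are described. Coordinates are on GRCm38, the assembly also called mm10.

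The comparison was knockout against wild type. Entrez-numbered genes with a mean of at least 1 FPKM over the 4 libraries were tested, which kept 9501 genes, 62.9% of those listed. Values as deposited were transformed to log2(FPKM + 1) and compared with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, using a moderated linear model whose prior variance follows the mean expression. The test was two-sided, without a block, and p-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold. The labels give no sign that a replicate number marks a shared animal or day, nor that the 2 libraries of a genotype come from separate animals or cultures. The p-values therefore measure only the spread between these libraries.

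A set of 37 gene lists was fixed, on pathways, macrophage states, markers of other cell types and RNA quality, together with the tests and most alternatives, before the data were examined. The 29 lists with at least 5 tested members were compared with all other tested genes by limma's camera, two-sided, with a preset correlation of 0.01 between genes and adjustment over the 29 lists. Camera with an estimated correlation and limma's fry, which asks whether a list moves on balance in 1 direction without reference to other genes, were run beside it. Each list's members past the threshold were counted over all tested genes and also adjusted over the list alone.

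The genes named in the text follow a rule. Fixed genes of the PERK pathway, serine synthesis and IL-4 activation were named whatever their values. In each direction, the 8 named genes with a mean of at least 5 FPKM and the smallest p were added, because fewer than 8 passed the threshold with non-overlapping libraries. Predicted genes were left out of this part. For each list described in detail, the 4 members with the smallest p were added. Not every gene that the rule takes is described in the text. Other genes are named as the most abundant member of a marker list or as chosen after their values were seen.

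The procedure was tested on simulated data with the same 9501 genes, variances drawn from the fitted model and 200 changed genes in each of 10 simulations. The changed genes were drawn only from the more highly expressed ones, with the change added on the log2 scale. The shares recovered therefore do not cover weakly expressed genes. Limma recovered 1.79% of genes changed 1.5-fold, 39.6% of those changed 2-fold and 95.2% of those changed 4-fold, and called 0.0366% of unchanged genes. With simulated genes that varied independently, preset camera called a list shifted by -0.3 on the log2 scale in 10 of 10 simulations, and camera with an estimated correlation did so in 0 of 10. A list that camera with an estimated correlation leaves uncalled may therefore still hold a shift of that size. In the real data the estimated correlation was 0.48 in the ATF4 list, 0.68 in the aminoacyl-tRNA synthetase list, 0.87 in the interferon list and 0.05 in the NRF2 list. These simulations therefore cannot show how often preset camera calls correlated lists falsely.

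Alternatives covered the scaling between libraries (median ratio and upper quartile), the filter on low values, the pseudocount, the variance trend, robust variance estimation, the threshold, a block on replicate number, genes listed in all 4 libraries, protein-coding named genes, and each library left out in turn. A library left alone in its group was assumed to vary like the other group. Median-ratio scaling with 1 library left out, and a fit on all listed features, were added after seeing the data.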

Results

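The study concerns PERK, the endoplasmic reticulum kinase encoded by Eif2ak3 that phosphorylates eIF2α under stress, as a metabolic regulator of immunosuppressive macrophages. Its deposited libraries compare IL-4-stimulated macrophages with and without PERK, 2 libraries per genotype. The wild-type libraries listed 48775 and 48335 features above zero and the knockout libraries 53411 and 80375, in the order of their replicate numbers. Entrez-numbered genes held 59.0% and 57.6% of all FPKM in the wild-type libraries. They held 54.8% in knockout replicate 1 and 41.1% in knockout replicate 2, which listed 29618 features found in no other library. The median log2 change of all tested genes, knockout minus wild type, was -0.14 in the deposited values and -0.0042 after median-ratio scaling. Log2 changes below are therefore given relative to the median gene unless stated otherwise. The p-values, and counts of genes under a p, come from the deposited values, which carry that shift.

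**Figure D1:**
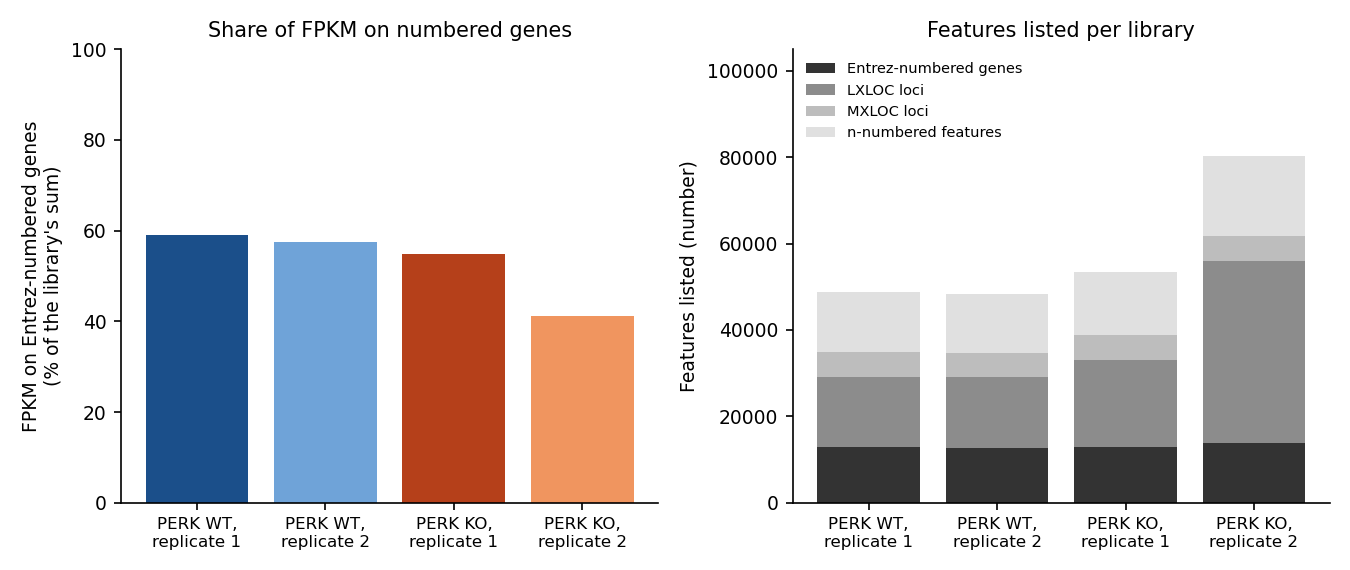
Share of all FPKM that falls on Entrez-numbered genes (percent) and number of features listed above zero, for each of the 4 libraries. Knockout replicate 2 stands apart, with 41.1% of FPKM on Entrez-numbered genes and 80375 features.

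The targeted gene was measured first, as a description of the genotypes. Eif2ak3 (Entrez 13666, chromosome 6, 70844484 to 70905241) stood at 9.89 ± 1.43 FPKM in wild type and 5.71 ± 1.18 FPKM in knockout macrophages (SD, n = 2 each). Its log2 change as deposited was -0.70 with a standard error of 0.18, or -0.56 relative to the median gene, and both knockout libraries lay below both wild-type libraries. So did 3386 of all 9501 tested genes as deposited, while 393 had both knockout libraries above. Lyz2 (Entrez 17105, chromosome 10, 117277541 to 117282272), the lysozyme gene into which LysMcre is inserted, stood at 663 ± 50.9 FPKM in wild type and 227 ± 36.5 FPKM in knockout (SD, n = 2 each). Its log2 change as deposited was -1.55 with a standard error of 0.22. Neither gene passed the threshold over all genes (limma adjusted p = 0.776 for Eif2ak3 and 0.413 for Lyz2), and gene-level FPKM cannot show which Eif2ak3 exons were lost.

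Across the transcriptome, Rpl3, a large-subunit ribosomal protein, and Smdt1, a regulator of the mitochondrial calcium uniporter, were the genes past the threshold. Rpl3 (Entrez 27367, chromosome 15, 80077781 to 80083406) measured 167 and 180.2 FPKM in the wild-type libraries and was listed in neither knockout library (limma adjusted p = 4.5e-06). Smdt1 (Entrez 69029, chromosome 15, 82346046 to 82349062) measured 49.0 and 55.9 FPKM in wild type and was likewise listed in neither knockout library (limma adjusted p = 1.9e-05). Of 9501 genes, 0 were higher and 2 lower at a limma adjusted p of 0.05. At an unadjusted p under 0.05 there were 401, 67 higher and 334 lower, against 475 that chance alone gives. After median-ratio scaling there were 299, 178 higher and 121 lower, so the balance of directions turned with the scaling. Limited to genes listed in all 4 libraries, limma called 0 genes, with 400 at an unadjusted p under 0.05. Without wild-type replicate 2 the calls numbered 43, 39 higher and 4 lower, and 16 of them were in the interferon list described below. Among the 29 gene lists tested, preset camera called 14, camera with an estimated correlation called 0 (lowest adjusted p = 0.922) and fry called 0 (lowest adjusted p = 0.243). In simulations, camera with an estimated correlation called a list shifted by -0.3 in 0 of 10. Its lack of calls here and below therefore cannot argue against a shift of that size.

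Other genes with small unadjusted p-values are given as values. Kitl, the ligand of the receptor KIT, measured 6.84 and 8.35 FPKM in wild type and 27.9 and 15.9 FPKM in knockout, a log2 change of +1.51 (SE 0.26, limma adjusted p = 0.776). Ly6a, a surface antigen that interferon induces, measured 1.00 and 4.30 FPKM in wild type and 19.0 and 7.46 FPKM in knockout, and passed the threshold without wild-type replicate 2 (limma adjusted p = 0.0163). The chemokine receptor gene Ccr2 measured 8.14 and 9.61 FPKM against 13.6 and 12.8 FPKM, and the Toll-like receptor gene Tlr1 measured 10.7 and 12.5 FPKM against 19.3 and 15.7 FPKM. Leng8, Srrm2, Gramd1a and Ide had log2 changes of +0.70, +0.87, +0.79 and +0.62. In the other direction, Hgsnat, a lysosomal acetyltransferase gene, measured 66.1 and 57.8 FPKM in wild type and 36.8 and 33.4 FPKM in knockout. Tnfsfm13, Ndufaf8, Srsf7 and Rasgrp3 had log2 changes of -0.59, -0.54, -0.48 and -0.67.

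Downstream of PERK, the transcription factor ATF4 drives stress-response genes, including genes of amino acid synthesis and transport. Of 28 tested members of the ATF4 list, 22 lay below the median gene, with a list median of -0.19. Asns, asparagine synthetase, measured 52.1 and 35.3 FPKM in wild type and 28.9 and 22.0 FPKM in knockout, a log2 change of -0.60 (SE 0.23). As deposited it was -0.74, and -0.47 without wild-type replicate 1, the library without which Gdf15 went from -0.72 to -0.45. Gdf15, Eif4ebp1 and Pck2 had log2 changes of -0.58, -0.39 and -0.39, and Atf4 itself -0.19, while Ddit3 had +0.13 (-0.01 as deposited) and Trib3 -0.24. The list fell relative to other genes by preset camera (adjusted p = 0.0039), but not with an estimated correlation (adjusted p = 0.922). Over all genes 0 members passed limma, as did 0 adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. Preset camera lost the call without wild-type replicate 1 (adjusted p = 0.325) and without knockout replicate 2 (adjusted p = 0.226), the library with 41.1% of FPKM on Entrez-numbered genes.

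Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and include ATF4 targets, were lower relative to other genes. Of 20 members, 18 lay below the median gene, with a median of -0.13. Cars measured 24.7 and 22.1 FPKM in wild type and 18.5 and 14.2 FPKM in knockout, and Gars, Mars1 and Yars had log2 changes of -0.34, -0.26 and -0.21. The list fell by preset camera (adjusted p = 2.6e-04), but not with an estimated correlation (adjusted p = 0.922), and not without wild-type replicate 1 (preset adjusted p = 0.0589). By limma, 0 members passed over all genes and 0 adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. After median-ratio scaling, the unadjusted limma p-values of Cars, Gars, Mars1 and Yars were 0.032, 0.048, 0.051 and 0.11.

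Serine synthesis and one-carbon metabolism, a pathway that ATF4 also feeds, held 17 of 26 members below the median gene. Psat1 measured 53.5 and 38.3 FPKM in wild type and 33.5 and 25.7 FPKM in knockout, and the mitochondrial folate enzyme gene Mthfd2 34.1 and 31.1 FPKM against 25.4 and 20.6 FPKM. Psph had a log2 change of -0.33. Phgdh, the first enzyme of the pathway, measured 38.3 FPKM in wild-type replicate 1 but 17.2 FPKM in wild-type replicate 2, against 17.6 and 14.8 FPKM in knockout, and Shmt2 was likewise highest in wild-type replicate 1. The list did not differ from other genes (preset camera adjusted p = 0.377). By limma 0 members passed over all genes or adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05.

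Among genes of IL-4 alternative activation, the state the cells had been stimulated into, Arg1 and Mrc1 had overlapping values in the 2 genotypes. Arg1, arginase 1, measured 1754 and 2061 FPKM in wild type and 2412 and 1324 FPKM in knockout. Mrc1 measured 758 and 1006 FPKM against 943 and 726 FPKM, and Retnla 627 and 596 FPKM against 550.1 and 522 FPKM. Mgl2, Irf4, Klf4, Batf3 and Cd200r1 had log2 changes of -0.21, -0.12, -0.26, -0.32 and -0.16, and Chil3 +0.12. As deposited, Klf4 went from -0.40 to -0.24 without wild-type replicate 1 and Batf3 from -0.46 to -0.16 without wild-type replicate 2. Kdm6b and Ppargc1b stayed under 1 FPKM in every library and were not tested. Of 39 tested members 24 lay above the median gene. The list's median and mean as deposited were negative (-0.08 and -0.06), while preset camera, which compares it with other genes, gave a higher level (adjusted p = 0.0277). That call was lost with an estimated correlation (adjusted p = 0.922), after median-ratio scaling (adjusted p = 0.140), with no filter on low values (adjusted p = 0.760), and without knockout replicate 1, wild-type replicate 1 or wild-type replicate 2 (adjusted p = 0.221, 0.325 and 0.0504). Limma called 0 members over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. After median-ratio scaling, Pdcd1lg2, also a member, was higher with an unadjusted limma p of 0.025.

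Among genes of immunosuppression and immune checkpoints, the PD-1 ligand genes had higher values in the knockout libraries, without passing the test. Cd274, which encodes PD-L1, measured 17.9 and 23.0 FPKM in wild type and 42.1 and 25.7 FPKM in knockout, a log2 change of +0.81 (SE 0.25). As deposited it was 0.67, with 0.33 without knockout replicate 1 and 1.02 without knockout replicate 2. Pdcd1lg2, which encodes PD-L2, measured 6.09 and 7.87 FPKM against 11.8 and 7.94 FPKM. Cd86 had a log2 change of +0.55 and Lilrb4a, an inhibitory receptor gene, -0.32. The list's median as deposited was negative (-0.06) and its mean positive (0.07). It rose against other genes by preset camera (adjusted p = 0.0039), but not with an estimated correlation (adjusted p = 0.922), and not without wild-type replicate 1 (preset adjusted p = 0.0717). Of 18 members, limma called 0 over all genes and 0 adjusted over the list alone, with 1 higher at an unadjusted p under 0.05. After median-ratio scaling, the higher Cd274, Pdcd1lg2 and Cd86 had unadjusted limma p-values of 0.011, 0.025 and 0.048. The lower Lilrb4a had 0.18, and none of these genes passed the threshold (adjusted p = 0.999 each).

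**Figure D2:**
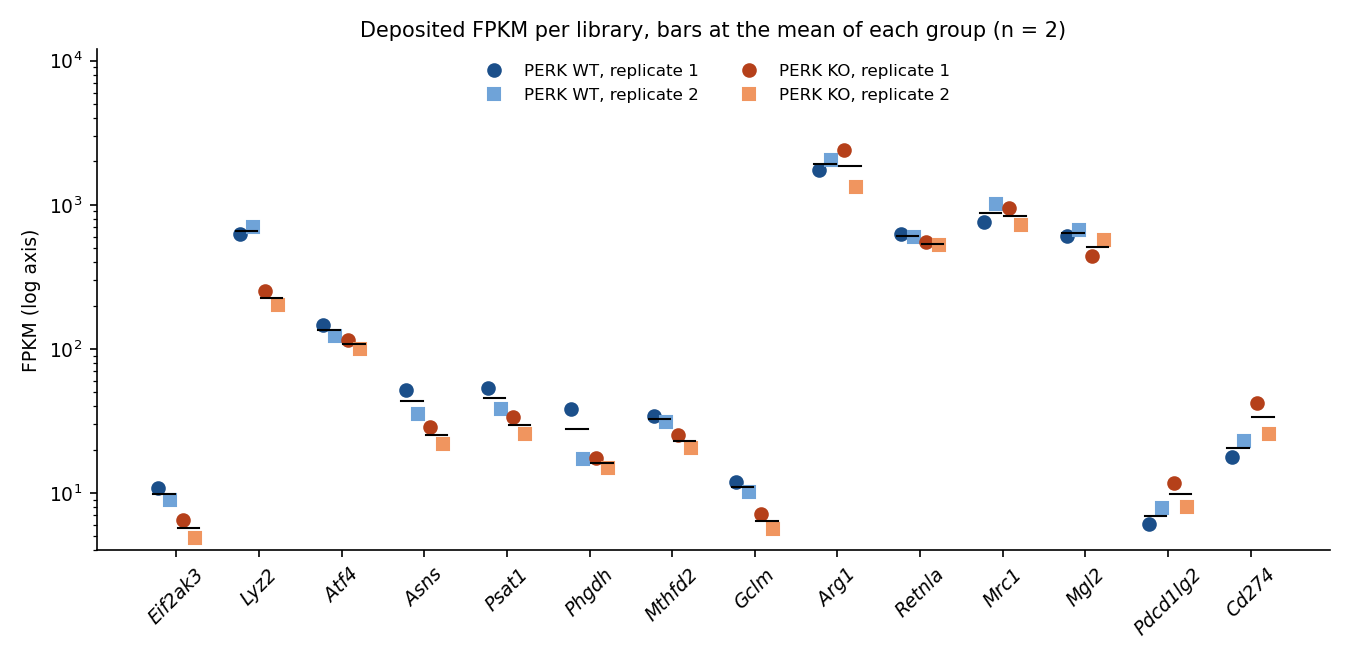
FPKM (log axis) of 14 named genes in each library, with points for the libraries and black bars for the group means (n = 2 per genotype). Both knockout libraries lie below both wild-type libraries for Eif2ak3, Lyz2, Atf4, Asns, Psat1, Mthfd2, Gclm, Retnla and Mgl2. Both lie above for Pdcd1lg2 and Cd274, and Phgdh, Arg1 and Mrc1 overlap between the genotypes. Of 9501 tested genes, 3386 had both knockout libraries below and 393 had both above.

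Among mitochondrial lists, the respiratory complexes passed preset camera. Of 75 nuclear-encoded subunits of respiratory complexes I to V, 55 lay below the median gene, with a median of -0.07. Ndufb8 measured 108 and 105 FPKM in wild type and 84.0 and 70.7 FPKM in knockout, and Uqcrq, Uqcr11 and Ndufs8 had log2 changes of -0.36, -0.26 and -0.23. The list fell by preset camera (adjusted p = 0.0277), but not with an estimated correlation (adjusted p = 0.922), nor without knockout replicate 2 or wild-type replicate 2 (preset adjusted p = 0.473 and 0.637), nor with a minimum mean of 5 FPKM (adjusted p = 0.131). The list stood lowest in knockout replicate 2, at -0.06 from its own mean after median-ratio scaling, the library with 41.1% of FPKM on Entrez-numbered genes. By limma 0 members passed over all genes or adjusted over the list alone, with 3 lower at an unadjusted p under 0.05. Lists of the tricarboxylic acid cycle, fatty acid oxidation, mitochondrial dynamics, and mitochondrial stress and proteases had medians of -0.05, -0.03, -0.03 and -0.06. None passed preset camera (adjusted p = 0.0545, 0.0545, 0.377 and 0.377), but all 4 were lower with no filter on low values (adjusted p = 0.0033, 0.0033, 0.0291 and 0.0492). The lists of the tricarboxylic acid cycle, fatty acid oxidation and mitochondrial stress also passed without knockout replicate 1 (adjusted p = 2.8e-04, 0.021 and 0.0438). Cpt1a, which admits fatty acids into mitochondria, had a log2 change of -0.20. Glycolysis genes had a median of -0.01 (adjusted p = 0.592), and the test was positive in sign although the median and mean as deposited were negative. Their level followed the replicate number. After median-ratio scaling it stood at 0.22 and -0.16 from the list's own mean in the wild-type libraries, and at 0.24 and -0.24 in the knockout libraries.

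In the other arms of the unfolded protein response, list medians lay close to that of all genes. The ATF6 and XBP1 list had a median of -0.05 over 39 members (preset camera adjusted p = 0.103). The list passed with no filter on low values (preset camera adjusted p = 0.0016), and also without knockout replicate 1. The chaperone gene Hspa5 measured 491 and 527 FPKM in wild type and 492 and 415 FPKM in knockout. The eIF2 kinase and phosphatase list had a median of -0.05 (adjusted p = 0.560). Histone demethylases and TET enzymes had a median of +0.02 (adjusted p = 0.872). As deposited its test was negative in sign, and after median-ratio scaling positive.

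Antioxidant genes controlled by NRF2 were lower in the knockout group relative to other genes, though single libraries overlapped for some members, such as Fth1 at 649 and 435 FPKM in wild type and 308 and 642 FPKM in knockout. All 22 tested members were below the median gene, as deposited and after median-ratio scaling, with a median of -0.23. Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, measured 11.96 and 10.1 FPKM against 7.19 and 5.60 FPKM, and 13.3 and 14.0 FPKM against 8.96 and 9.08 FPKM. Prdx1 and Txnrd1, of peroxide and thioredoxin reduction, had log2 changes of -0.37 and -0.35. The list fell by preset camera (adjusted p = 6.6e-08), but not with an estimated correlation (adjusted p = 0.922). By limma 0 members passed over all genes, with 9 lower at an unadjusted p under 0.05. Adjusted over the list alone 8 were lower, and 0 after median-ratio scaling.

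Genes of the type I interferon response stood higher in the knockout libraries, and lowest in wild-type replicate 1. Of 36 members 35 lay above the median gene, with a median of +0.94. Mx1 measured 2.85 and 8.10 FPKM in wild type and 13.4 and 12 FPKM in knockout, and Ifit2 2.39 and 7.93 FPKM against 12.1 and 11.02 FPKM. Mx2 and Ifi205 had log2 changes of +1.03 and +0.93. Relative to its mean over the libraries, the list's median stood at -1.03 and 0.21 in the wild-type libraries and at 0.43 and 0.51 in the knockout libraries, after median-ratio scaling. The list rose by preset camera (adjusted p = 1.6e-40), but not with an estimated correlation (adjusted p = 0.922). Without wild-type replicate 1 its median was +0.26 (preset adjusted p = 2.3e-08), and without wild-type replicate 2 it was +1.47, with Mx1 and Ifit2 past the threshold (limma adjusted p = 0.00486 and 0.00429). Limma called 0 members over all genes and 0 adjusted over the list alone, with 7 higher at an unadjusted p under 0.05.

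Pro-inflammatory genes, the opposite activation state, included members on both sides. Ccl4 and Nfkbia had log2 changes of -0.26 and -0.13, while the acute-phase gene Saa3 measured 2.48 and 14.0 FPKM in wild type and 41.8 and 9.49 FPKM in knockout. The list rose by preset camera (adjusted p = 0.0039), but not with an estimated correlation (adjusted p = 0.922), after median-ratio scaling (adjusted p = 0.0590) or without knockout replicate 1 (adjusted p = 0.588). MHC class II presentation held all 9 members above the median gene, with a median of +0.40 (preset adjusted p = 1.1e-04, and 0.922 with an estimated correlation). H2-Aa measured 22.8 and 10.3 FPKM in wild type and 40.4 and 14.3 FPKM in knockout, and H2-Eb1, H2-Ab1 and Cd74 were likewise higher in replicate 1 than in replicate 2 of each genotype. The call was lost without knockout replicate 1 (adjusted p = 0.675) and without wild-type replicate 2 (adjusted p = 0.170). Limma called 0 members of either list over all genes or adjusted over the list alone, with 1 pro-inflammatory gene lower at an unadjusted p under 0.05. That gene, Ccl4, had an unadjusted limma p of 0.076 after median-ratio scaling, and the higher Cd86 had 0.048.

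**Figure D3:**
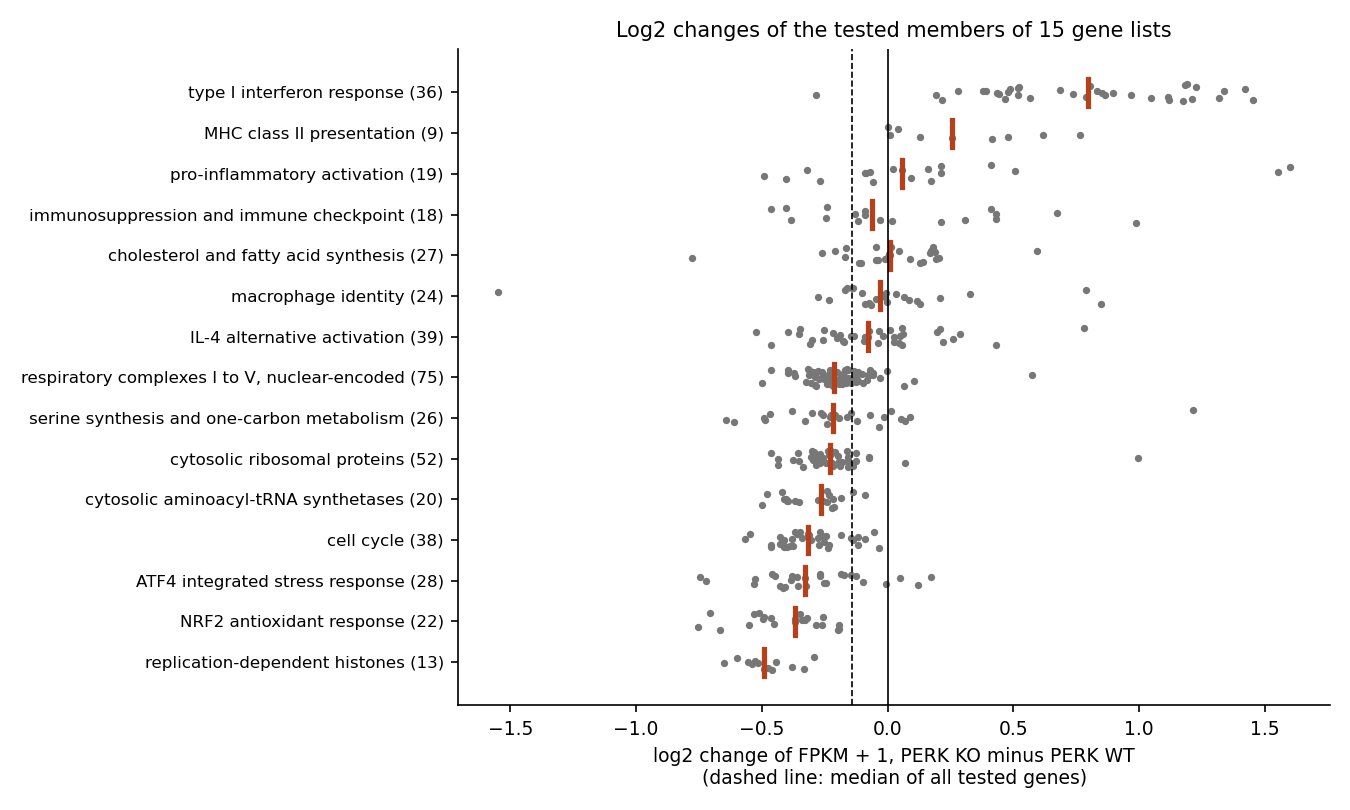
Log2 change, knockout minus wild type as deposited, of the tested members of 15 gene lists (grey points, Rpl3 not drawn), with each list's median (orange bar) and the median of all tested genes, -0.14 (dashed line). All 22 NRF2 members lie left of the dashed line and 35 of 36 interferon members lie right of it.

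**Figure D4:**
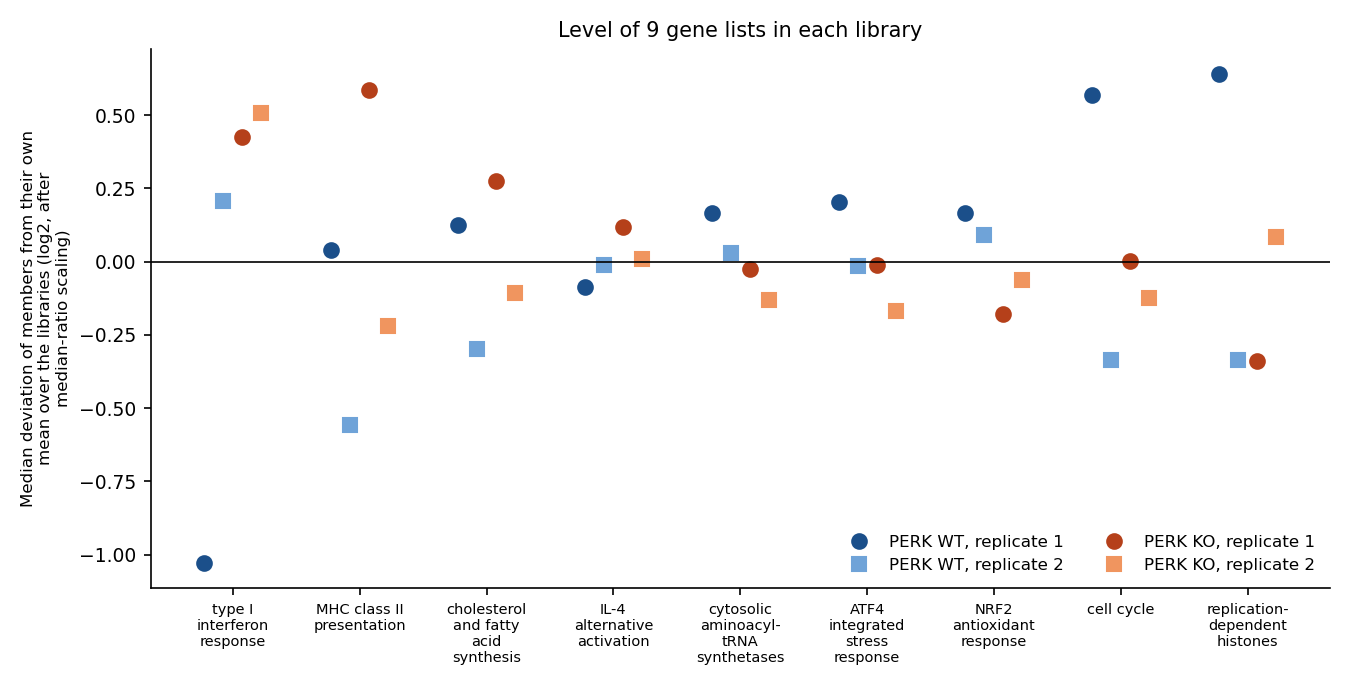
Median deviation of the members of 9 gene lists from their own mean over the libraries (log2, after median-ratio scaling), for each library of each genotype. The interferon list stands at -1.03 in wild-type replicate 1 and between 0.21 and 0.51 in the other libraries.

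Macrophage markers were described beside those of other marrow cells. The macrophage identity list had a median of +0.11 relative to the median gene (-0.03 as deposited, mean -0.02, with a positive test). It rose by preset camera (adjusted p = 0.0253), but not with an estimated correlation (adjusted p = 0.922), after median-ratio scaling (adjusted p = 0.10) or without knockout replicate 2 (adjusted p = 0.22). Without wild-type replicate 1 it turned to the lower side (adjusted p = 0.101). Fcgr1, an Fc receptor gene, measured 7.27 FPKM in wild-type replicate 1 and 33.6, 34.0 and 25.5 FPKM in wild-type replicate 2 and the knockout libraries, and passed the threshold without wild-type replicate 2 (limma adjusted p = 0.0111). Aif1 and Ms4a7 were also lowest in wild-type replicate 1, at 3 and 8.49 FPKM. Limma called 0 members over all genes and Lyz2 alone as lower when adjusted over the list alone, which was also the 1 member at an unadjusted p under 0.05.

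Lists of other cell types mostly had too few expressed members to test. The most abundant granulocyte, monocyte, lymphocyte and stromal markers were Mmp9, Ccr2, Cd79b and Vwf, with means of 5.51, 11.1, 1.40 and 11.1 FPKM over the libraries. Mast cell and basophil markers stayed at or below 0.11 FPKM in every library, the highest value being that of Ms4a2 in knockout replicate 2. Among erythroid and megakaryocytic markers, Pf4 averaged 437 FPKM, but the median of the 8 listed members was at most 0.06 FPKM in every library. The most abundant dendritic cell marker was Bst2, also a member of the interferon list, at 232 FPKM, and the most abundant osteoclast marker was Atp6v0d2, also a member of the lysosome list, at 232 FPKM. Dendritic cell and osteoclast markers did not differ from other genes (preset camera adjusted p = 0.970 and 0.662), nor did immediate early genes, which respond to handling (adjusted p = 0.0876). No mitochondrially encoded transcript and no small structural RNA of the fixed lists was listed in any library.

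Cytosolic ribosomal proteins held 45 of 52 members below the median gene, with a median of -0.09. They fell by preset camera (adjusted p = 0.0173), but not with an estimated correlation (adjusted p = 0.922), and turned upward without wild-type replicate 2 (adjusted p = 0.978). Limma called 1 member lower, Rpl3, over all genes and adjusted over the list alone. On genes listed in all 4 libraries, which leaves out Rpl3, the list did not pass preset camera (adjusted p = 0.0722). Rpl8 and Rps23 had log2 changes of -0.30 and -0.19. Rps12, Rpl4, Rpl11 and Rpl27 reached at most 4.71, 4.29, 7.83 and 3.92 FPKM in any library, against list medians between 274 and 377 FPKM. Without wild-type replicate 2, Rps12 passed the threshold (limma adjusted p = 0.027).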

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

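The tests of sequencing depth, of wild-type replicate 1, of scaling and of a linked chromosome segment were chosen only after the result was seen.

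Knockout replicate 2 listed 28400 features without an Entrez number that appeared in no other library. A co-varying set of 27 other such features was chosen by level, fold and profile. Each had at least 10 FPKM here, 100 times wild-type replicate 1, and a correlation above 0.98 with the median profile. Their excess over wild-type replicate 1 and shared profile follow from that choice. They took 12.5% of this library's FPKM, against 0.98% in knockout replicate 1 and at most 0.131% in wild type. Both groups of features stood out as signal in data outside the comparison. Deeper sequencing as the whole reason is argued against, since features listed only in this library had a median of 0.29 FPKM and those listed only in another library 0.10 to 0.18, but a part stays open, as 1673 Entrez-numbered genes stood at 0.05 FPKM or less here against 1043 to 1127, and 1218 were listed only here against 188 to 262. The 27 features are not the whole reason for the low share on Entrez-numbered genes, which without them was 47.0%, against 55.4% to 59.0% elsewhere. The rest of the 59 features that passed the level and fold rules were not left out. Background from unspliced RNA or genomic DNA is a candidate explanation: of 261 genes from families silent in macrophages, such as olfactory receptors, that were listed in at least 1 library, 218 were listed here, against 36 to 46 in each of the others. No biological explanation of this library's makeup was tested.

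Interferon-response genes were higher in the knockout libraries. Scaling between the libraries is argued against, because the list's median log2 change was 0.91 after median-ratio scaling. Without wild-type replicate 1 the median, relative to all genes, was 0.26, so a low level in that library may make up most of the difference and a genotype difference cannot be told apart from it with 1 wild-type library left. The preset camera adjusted p, over scalings and left-out libraries, ranged up to 2.3e-08, but was 0.922 with an estimated correlation. A response to the loss of PERK stays open and untested.

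Rpl3 and Smdt1 were listed in neither knockout library. Assignment of reads to other features could account for this: 2 unnamed features outside the co-varying set gained at least 50 FPKM in both knockout libraries, but 1 fell as far in the other direction, so the count decides nothing. Both genes lie on chromosome 15, 2.27 Mb apart, and a linked segment that differs between the genotypes is a second candidate explanation. With Rpl3 and Smdt1 left out, their 5 Mb window held 2 of 49 genes with p under 0.01, as the fullest other window did. Of the shuffles, 0.997 gave a window as full. Each shuffle took the fullest of 510 windows, whereas this window was fixed by the 2 genes. The comparison therefore cannot decide whether a linked segment differs. Of 52 listed ribosomal protein genes, 4 stayed below 10 FPKM in all libraries of both genotypes, Rpl3 not among them. The list medians lay between 274 and 377 FPKM. A low or missing value alone therefore cannot show that a transcript was lost. A biological loss of both transcripts stays open and untested.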

How the results depend on the processing

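Median-ratio scaling with 1 library left out and the fit on all listed features were chosen only after the result was seen.

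The count of 2 genes past the threshold stood at 2 under both scalings, no filter, a pseudocount of 0.1, robust variances, protein-coding named genes, an adjusted p of 0.1, a minimum of 2-fold, all listed features and median-ratio scaling with KO replicate 2 or WT replicate 1 left out, and at 3 with a minimum mean of 5 FPKM or without the variance trend. Rpl3 and Smdt1 were among the calls in each of these. Limited to genes listed in all 4 libraries the counts were 0 in all and 0 lower, which the construction shows, since both genes are then left out. With a block on replicate number, limma called 14 genes, 6 higher and 8 lower, Kitl among the higher (adjusted p = 0.0153). The labels do not say what libraries of the same number share, and over all genes their deviations from the group means correlated at 0.070. Eif2ak3 stayed lower under every alternative, without passing. The NRF2 and interferon lists stayed past preset camera under each scaling and each left-out library. Depth is unknown, so what it limits cannot be stated. For the results below the cause was not tested, except where stated. Log2 changes in this part are not taken relative to the median gene.

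With an estimated correlation, the IL-4 alternative activation, ATF4 integrated stress response and respiratory complexes lists each had an adjusted p of 0.922. By fry, ATF4 integrated stress response and respiratory complexes had 0.663 each, and these lists had the opposite sign to camera, which follows from the tests, since fry takes no account of the shift of -0.14 common to all genes: IL-4 alternative activation 0.832, glycolysis 0.832, liver X receptor targets 0.832, extracellular matrix 0.717, macrophage identity 0.878, dendritic cells 0.832, osteoclasts 0.663 and immediate early genes 0.663.

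After median-ratio scaling the log2 change was positive for Ddit3 (0.14), Arg1 (0.064), Chil3 (0.098) and Mrc1 (0.076), where the deposited values gave a negative one. Relative to the median gene these 4 were already positive, so the turn is the shift of -0.14 common to all genes. The IL-4 alternative activation list was no longer past the threshold (adjusted p = 0.140), and the direction turned for histone demethylases (0.990), liver X receptor targets (0.973), extracellular matrix (0.868) and dendritic cells (0.871). After upper-quartile scaling the log2 changes of these genes were 0.14 for Ddit3, 0.059 for Arg1, 0.095 for Chil3 and 0.071 for Mrc1. The adjusted p was 0.127 for IL-4 alternative activation and 0.081 for macrophage identity, and the direction turned for histone demethylases (0.975), liver X receptor targets (0.963), extracellular matrix (0.896) and dendritic cells (0.900).

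With no filter, IL-4 alternative activation came to an adjusted p of 0.760, and liver X receptor targets (0.565) and osteoclasts (0.997) turned. With a minimum mean of 5 FPKM respiratory complexes came to 0.131, and without the variance trend IL-4 alternative activation came to 0.0592. With the block, respiratory complexes came to 0.234, and glycolysis (0.918) and dendritic cells (0.605) turned. On all listed features serine synthesis fell (0.00159), and these turned from higher to lower: IL-4 alternative activation 0.281, glycolysis 0.103, liver X receptor targets 0.185, extracellular matrix 0.185, macrophage identity 0.635, dendritic cells 0.281, osteoclasts 0.281 and immediate early genes 0.628.

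Other called lists were lost in these settings. With no filter, cholesterol and fatty acid synthesis came to an adjusted p of 0.448 and macrophage identity to 0.559. With a minimum mean of 5 FPKM cell cycle came to 0.0543. Ribosomal proteins came to 0.234 with the block and 0.0722 on genes listed in all 4 libraries. On all listed features immunosuppression came to 0.804, pro-inflammatory activation to 0.832, MHC class II to 0.124 and cholesterol and fatty acid synthesis to 0.939. With KO replicate 2 left out under median-ratio scaling, aminoacyl-tRNA synthetases came to 0.0583, cell cycle to 0.0846 and macrophage identity to 0.434. With WT replicate 1 left out under it, immunosuppression came to 0.177 and pro-inflammatory activation to 0.15. With no filter 6 further lists passed: the ATF6 and XBP1 unfolded protein response (0.0016), tricarboxylic acid cycle (0.0033), fatty acid oxidation (0.0033), mitochondrial dynamics (0.0291), mitochondrial stress (0.0492) and extracellular matrix (0.0112). On all listed features 9 further lists passed: serine synthesis and one-carbon metabolism, ATF6 and XBP1 unfolded protein response, eIF2 kinases, tricarboxylic acid cycle, fatty acid oxidation, mitochondrial dynamics, mitochondrial stress, histone demethylases and lysosome and autophagy. Without knockout replicate 1, dendritic cell markers, immediate early genes and glycolysis also passed. Glycolysis passed without knockout replicate 2 or wild-type replicate 1 as well, and dendritic cell markers without wild-type replicate 1.

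Under median-ratio scaling with KO replicate 2 left out, the log2 change turned positive for Ddit3 (0.11), Trib3 (0.10), Arg1 (0.41), Chil3 (0.67), Mrc1 (0.17) and Hspa5 (0.014). IL-4 alternative activation (adjusted p = 0.0846), ATF4 integrated stress response (0.231) and respiratory complexes (0.784) did not pass. The direction turned for the ATF6 and XBP1 unfolded protein response (0.594), eIF2 kinases and phosphatases (0.867), tricarboxylic acid cycle (0.594), mitochondrial stress (0.722), liver X receptor targets (0.594), dendritic cells (0.0347), osteoclasts (0.848) and immediate early genes (0.911).

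Under median-ratio scaling with WT replicate 1 left out, the log2 change turned positive for Ddit3 (0.17), Trib3 (0.0022), Phgdh (0.064), Shmt2 (0.072), Retnla (0.0059), Irf4 (0.35), H2ac10 (0.0031) and H4c4 (0.12), and negative for Fcgr1 (-0.030). IL-4 alternative activation (adjusted p = 0.516) and ATF4 integrated stress response (0.298) did not pass. The direction turned for serine synthesis (0.717), histone demethylases (0.648), liver X receptor targets (0.053), cell cycle (1.8e-05), extracellular matrix (0.648), macrophage identity (0.0331), dendritic cells (0.0272) and replication-dependent histones (0.0331).

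With each library left out in turn, on the values as deposited, the calls ranged from 2 to 43, from 0 to 39 higher and from 2 to 4 lower, the highest of each without wild-type replicate 2. Of 86 named genes tested, the log2 change of 46 moved by over 1.5 times when some library was left out. It ranged from -0.055 to 0.045 for Ddit3, -0.81 to 0.052 for Trib3, -0.52 to 0.34 for Arg1, -0.66 to 0.63 for Chil3, -0.28 to 0.13 for Mrc1 and -0.72 to 0.21 for Irf4. It ranged from -0.10 to 1.34 for H2-Aa, -0.13 to 1.09 for H2-Ab1, -0.15 to 0.99 for Cd74, -0.20 to 1.39 for Scd1 and -0.18 to 1.88 for Fcgr1.

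The adjusted p of preset camera over these left-out libraries ranged from 0.0324 to 0.325 for IL-4 alternative activation, 2.4e-05 to 0.325 for ATF4 integrated stress response, 0.0558 to 0.717 for serine synthesis, 0.0011 to 0.927 for the ATF6 and XBP1 unfolded protein response, 0.195 to 0.938 for eIF2 kinases and phosphatases and 7.8e-04 to 0.637 for respiratory complexes. It ranged from 2.8e-04 to 0.927 for the tricarboxylic acid cycle, 0.021 to 0.529 for fatty acid oxidation, 0.22 to 0.818 for mitochondrial dynamics, 4.8e-04 to 0.177 for glycolysis, 0.0438 to 0.927 for mitochondrial stress, 0.427 to 0.852 for histone demethylases, 1.5e-11 to 0.968 for cholesterol and fatty acid synthesis and 0.10 to 0.698 for liver X receptor targets. For lysosome and autophagy it ranged from 0.287 to 0.927, cell cycle 7.4e-19 to 0.308, macrophage identity 3.4e-07 to 0.22, dendritic cells 0.00939 to 0.10, osteoclasts 0.282 to 0.991, immediate early genes 0.00718 to 0.927, ribosomal proteins 1.7e-04 to 0.978 and replication-dependent histones 8.9e-14 to 0.597.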

Other observations

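The comparison of splits and the features singled out below were chosen only after the result was seen.

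Cholesterol and fatty acid synthesis genes followed the replicate number more than the genotype. The list's median deviation from its own mean, after median-ratio scaling, was 0.12 and 0.27 in replicate 1 of wild type and knockout, and -0.30 and -0.11 in replicate 2. Scd1, the stearoyl-CoA desaturase gene, measured 4.67 and 0.89 FPKM in wild type and 7.16 and 2.00 FPKM in knockout. Fdft1 and Acly had log2 changes relative to the median gene of +0.33 and -0.07, and Mvk, mevalonate kinase, -0.64. Relative to the median gene the list's median was +0.15, and it rose by preset camera (adjusted p = 0.0021), but not with an estimated correlation (adjusted p = 0.922). The call was lost without knockout replicate 1 (adjusted p = 0.968), and the direction turned without wild-type replicate 2 (adjusted p = 0.438).

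Proliferation genes were highest in wild-type replicate 1. The cell cycle list stood at 0.57 there and between -0.33 and 0.00 in the other libraries, and replication-dependent histones at 0.64 against -0.34 to 0.08. The replication licensing genes Mcm6, Mcm3 and Mcm2 had log2 changes of -0.24, -0.23 and -0.22, and Cdc6 -0.29. H4c4 measured 359 FPKM in wild-type replicate 1 and 196, 189 and 192 FPKM in the others, and H2bc4, H4c8 and H2ac10 were also highest there. Both lists fell by preset camera (adjusted p = 0.0274 and 0.0173) but not with an estimated correlation (adjusted p = 0.922 for each). Without wild-type replicate 1 the cell cycle list rose instead (adjusted p = 5.9e-05) and the histone list turned upward (adjusted p = 0.0717). The cell cycle call was also lost without knockout replicate 1 (adjusted p = 0.308) or knockout replicate 2 (adjusted p = 0.22), and the histone direction turned without knockout replicate 1 (adjusted p = 0.597). Limma called 0 members of the cholesterol, cell cycle and histone lists over all genes or adjusted over each list alone, with 1 of each lower at an unadjusted p under 0.05.

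Liver X receptor targets, lysosome and autophagy genes, and extracellular matrix genes had medians of -0.09, -0.03 and -0.02 relative to the median gene, and none differed from other genes (preset camera adjusted p = 0.771, 0.662 and 0.662). For liver X receptor targets and extracellular matrix genes the test was positive in sign while the median and mean as deposited were negative.

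An unnamed feature, MXLOC_018671, measured 1122 and 1272 FPKM in wild type and 490.4 and 363 FPKM in knockout. LXLOC_093854 and MXLOC_146744 went the other way, from 192 and 196 FPKM to 295 and 578 FPKM, and from 197 and 198 FPKM to 349 and 308 FPKM.

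With 4 libraries there are 3 splits into pairs, too few for a share under 0.05. The real split gave 401 genes at an unadjusted p under 0.05 and the highest of the others 581, with 2 of the 3 splits at or above the real value. That other split groups libraries by replicate number and gave 16 genes at a limma adjusted p of 0.05 against 2. The labels do not say what libraries of the same number share, and the cause was not tested.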
